A study of Mus musculus with 2 samples.

How the data were processed

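The measurements were taken on 2 Affymetrix arrays of total RNA from CD41-sorted cells derived from the Bry-GFP mouse embryonic stem cell line, 1 array of cells cultured with DMSO and 1 of cells cultured with 300 nM of the LSD1 inhibitor compound B. Per the labels' protocols, RNA was isolated with a column kit, single-stranded cDNA was made from amplified cRNA, and the cDNA was fragmented and labelled with biotin. The groups were taken from the sample titles.

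The deposited table holds 1 value per probeset and array, on a scale read here as log2 intensity. The log base was judged from the values, which run from 0.157 to 13.5, since another usual base would put the brightest probesets beyond the range of a scanner. The summarisation and normalization that the authors used are not given in the sources used here. The sorted values of the 2 arrays differ by at most 0.085 at equal rank, as they do after a quantile normalization. The median value was 3.18 in the control array and 3.16 in the inhibitor array. The table has 1048575 probesets and, with its header, 1048576 lines, which equals the row limit of a common spreadsheet program. Probesets beyond that line, if the array has them, were not analysed here, so a gene may be measured on part of its probesets or be missing. The table gives no detection call, so a dim value cannot be told from background probeset by probeset.

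Gene names came from a platform annotation table of the array. It names 275842 of the probesets, 270105 with 1 gene symbol and 5737 with several, and leaves 772733 without a name. Probesets with several symbols were not used in the main setting. Of 22133 symbols, 17905 were current in the RefSeq gene table of the mouse assembly GRCm38.p6, 4167 were older and were updated through its synonyms, and 61 had no match and were kept. This gave 21947 genes. No coordinates are given because the genome build behind the probesets is not named in the files.

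The values were used as deposited in log2, with no further scaling. A probeset counted as bright if the higher of its 2 values was at or above the median of all values in the table, 3.17, which 208583 of the probesets with 1 gene were (77.2%). A gene was measured if it had at least 4 bright probesets, which 15087 genes had, with a median of 10 probesets. Its level in an array was the median of its bright probesets there. Its difference was the median of the differences of these probesets, inhibitor minus control, so it need not equal the gap between the 2 levels. A fold is 2 to the power of that difference. A gene passed the size rule with a difference of at least 1 in log2, which is 2-fold, and at least 75% of its bright probesets in the same direction. The SD over a gene's probesets was 0.60 in the median gene. Its sources were not separated, and it is no replicate error. With 1 array per group there are no p-values, no errors between samples and no adjusted values. Odd-ranked and even-ranked probesets gave gene differences that correlated at r = 0.55 across 10350 genes, which are not independent replicates. Of 199 genes past the size rule that could be split, 116 passed it in both parts.

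The 22 gene lists, 463 genes of which 384 were measured, were fixed before the data were examined, as were the rules, the alternatives and the rule for named genes. A list was described by the median difference of its measured members and the percentile of that median among 10000 random lists of the same size matched on level in 20 bins of genes. The rule named the 15 genes with the largest difference in each direction among genes past the size rule, leaving out clones and predicted genes and keeping at most 3 of a gene family. It also named 16 preset genes around LSD1, Gfi1 and blood emergence, up to 4 members of each list with the largest absolute difference, and all members past the size rule. This came to 139 genes. Another 7 lists and 3 alternatives were added after the data were seen. Of these lists, 4 were also run without the genes that led to them or that the erythroid list holds.

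The alternatives fixed in advance were each array centred on its median, quantile normalization of the 2 arrays, removal of a level-dependent trend (lowess with a span of 0.2), no filter on dim probesets, a filter at the 75th percentile of all values, the mean in place of the median over probesets, the brighter probesets of each gene alone, at least 1 or at least 8 bright probesets, probesets with several genes kept, values below the 20th percentile raised to it, odd-ranked or even-ranked probesets alone, a 1.5-fold or 3-fold threshold, no direction rule, the mean over list members, and random lists not matched on level. The added ones were values below the table's median raised to it, the median gene difference set to 0, and lists without members that another list also holds. Each was run alone, with 2000 random lists per list. The way in which a list's median was judged to depend on a setting was also settled after a first version had been seen, as stated with those results.

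The gene and list steps were tested on simulated data before use. Of 50 genes changed 2-fold among 15087 simulated genes, 33 passed the size rule (66%), and all 50 did at 3-fold, at 4-fold and at 8-fold. Of 14887 unchanged simulated genes, 55 passed it (0.369%). Of 200 unchanged simulated lists of 20 genes, 11 lay outside the central 95% of random lists (5.5%). The simulation shuffled the spread of probesets within genes and held no variation of whole genes between cultures, sorts or arrays. These shares therefore give no rate of false calls between 2 samples. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 for the lowess and matplotlib 3.10.9 for the plots.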

Results

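The series compared mouse cells cultured with and without an inhibitor of LSD1, the histone demethylase encoded by Kdm1a. Embryonic stem cells of the Bry-GFP line, which carry a GFP reporter in the mesoderm gene Brachyury, were grown as embryoid bodies, and FLK1-positive mesoderm cells were isolated on day 3. These cells were cultured with the solvent DMSO or with 300 nM of an LSD1 inhibitor known here by its code name, compound B. On culture day 2 the CD41-positive compartment was sorted from each culture, and its total RNA was hybridised to an Affymetrix array. The labels call the cells hemogenic endothelium, the endothelium that gives rise to blood cells. CD41, the sort marker, is an integrin of early blood cells and of megakaryocytes encoded by Itga2b. There was 1 array per condition and so no replicate. All differences below describe these 2 arrays, no test between conditions was possible, and the number of arrays limits the precision. An SD beside a gene is the spread over the probesets of that gene within the 2 arrays.

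The title of the series concerns Gfi1 proteins, repressors that recruit LSD1 while blood precursors emerge. The comparison of the inhibitor array with the control array addresses which transcripts differ in CD41-positive cells when LSD1 is inhibited. Genes of the endothelium, the transcription factors Gfi1, Gfi1b and Gata2 and the genes Id1, Id2 and Id3 were higher in the inhibitor array, and genes of red cells and some of platelets were lower. Of 15087 measured genes, 259 were at least 2-fold higher in the inhibitor array and 85 were at least 2-fold lower, with at least 75% of their probesets in the same direction. Another 17 genes met the size but not the direction requirement. The median difference of all measured genes was 0.06 on the log2 scale, and the central 90% of genes lay between -0.50 and 0.68. The gene levels of the 2 arrays correlated at r = 0.965 across genes, which are not independent replicates. Among the genes past the size rule, 32 of the 259 higher genes lay below the table's median value in the control array, and 20 of the 85 lower genes lay below it in the inhibitor array. Counts past the size rule depended on how many bright probesets a gene needed. With at least 1 in place of at least 4, 641 genes were higher and 439 lower. Of 80 named genes past the rule, 57 passed it, at 2-fold, in every alternative that measured them, the 3-fold threshold not included. The 23 that did not were Trim10, Pf4, Rec114, Aadacl2fm1, Lyve1, Erg, Sox18, Rasip1, Thsd1, Efnb2, Klf1, Cd53, Il10ra, Slc25a37, Car2, Kel, Slc4a1, Dcn, Gata4, Klf2, Dppa4, Irf7 and Egln3.

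**Figure D1:**
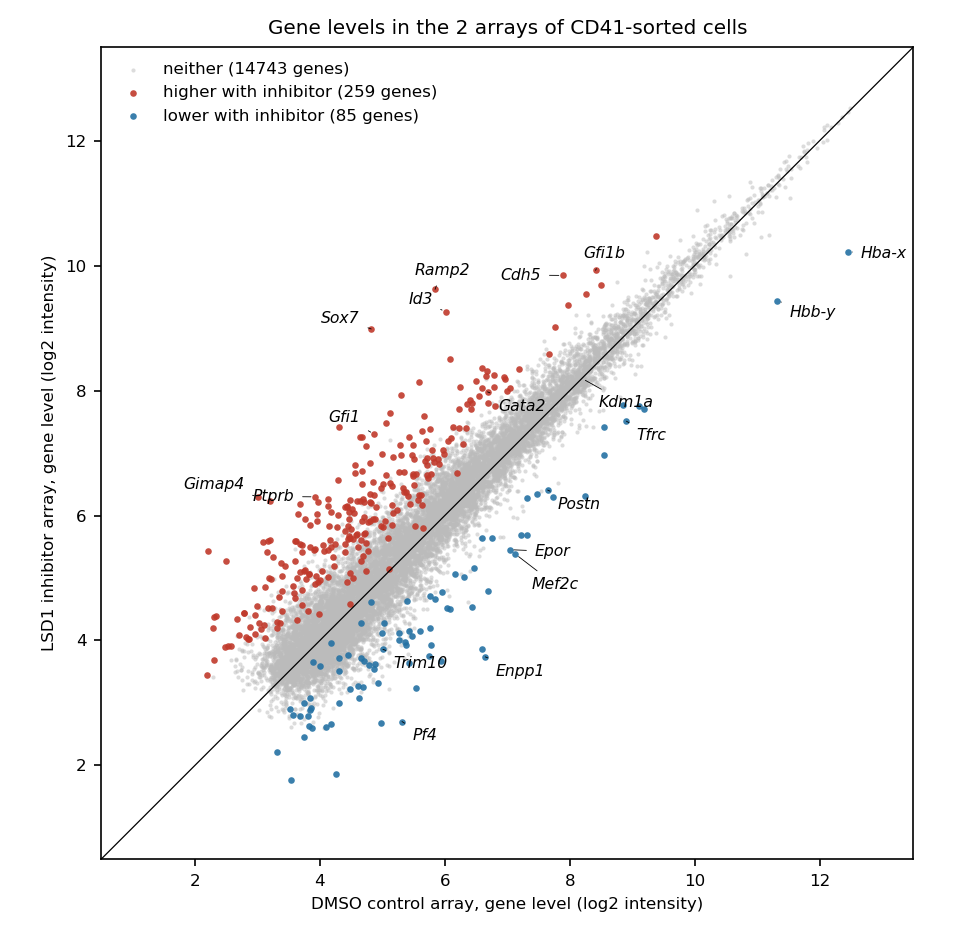
Gene levels (log2 intensity, median over the bright probesets of a gene) in the DMSO control array on the horizontal axis and the LSD1 inhibitor array on the vertical axis, with the line of equal levels. Each point is 1 of 15087 genes: 259 in red were at least 2-fold higher with the inhibitor, 85 in blue at least 2-fold lower, and Kdm1a lies near the line at 8.19 and 8.20.

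The largest difference upward was that of Sox7, a transcription factor of endothelium and hemogenic endothelium, which was 14.3-fold higher in the inhibitor array (log2 difference 3.84, SD 1.67 over 5 probesets). Gpm6a, a membrane glycoprotein best known from neurons, was 9.75-fold higher (3.29, SD 1.36 over 10 probesets). Id3, an inhibitor of basic helix-loop-helix transcription factors, was 9.46-fold higher (3.24, SD 0.74 over 4 probesets). Gimap4, a GTPase of the lymphocyte GIMAP family, differed by 3.22 (SD 1.13), with a control level of 3.01 that was below the table's median value of 3.17. Rasgrp3, which activates Ras, differed by 2.98, Ramp2, a part of the adrenomedullin receptor, by 2.92, and Ptprb, the endothelial receptor phosphatase VE-PTP, by 2.63, with 40 of its 40 probesets higher. The rest of the 15 genes furthest up were Oit3 (2.70), the matrix protein fibrillin 1 gene Fbn1 (2.68, 61 of 64 probesets higher), the ADP-ribosyltransferase gene Parp8 (2.55), Rgl1 (2.51), lipoprotein lipase gene Lpl (2.45), Gfi1 (2.43), Tfec (2.41) and Il2rg, the shared receptor chain of several interleukins (2.39).

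The largest difference downward was that of Enpp1, an ectonucleotide pyrophosphatase, which had a level of 6.65 in the control array and 3.74 in the inhibitor array (log2 difference -2.86, SD 0.90, 23 of 23 probesets lower). Of the 15 genes furthest down, 4 are in the erythroid list: Trim10, Hbb-b1, Hbb-y and Epor. Trim10, a RING protein of erythroid cells, differed by -2.51, the embryonic beta-like globin gene Hbb-y by -1.89 and the erythropoietin receptor gene Epor by -1.64. The difference of the beta globin gene Hbb-b1, -2.39 over 4 probesets, is uncertain because near-identical paralogs could bind the same probes. The platelet factor 4 gene Pf4 (-2.29) and the ATP receptor gene P2rx1 (-1.66) are in the megakaryocyte and platelet list. The others were the urea transporter gene Slc14a1 (-2.36), the carbonic anhydrase gene Car1 (-2.31), Rec114 (-2.15), the acid phosphatase gene Acp5 (-2.15), the manganese exporter gene Slc30a10 (-1.81), Aadacl2fm1 (-1.77), the actin-capping tropomodulin gene Tmod1 (-1.74) and the hyaluronan receptor gene Lyve1 (-1.61). The inhibitor levels of Car1, Pf4, Rec114, Aadacl2fm1 and Lyve1 lay below the table's median value, so the sizes of these 5 differences rest on dim values. With values below the table's median raised to it, Pf4 was at -0.77 and Lyve1 at -0.62. When dim probesets were kept, Rec114 was at -0.67 and Aadacl2fm1 turned to 0.03. Trim10 was at -0.53 with its even-ranked probesets alone.

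Kdm1a mRNA, which does not check the treatment because the inhibitor acts on the protein, was at 8.19 in the control array and 8.20 in the inhibitor array (difference 0.14, SD 0.56 over 22 probesets). Gfi1 was 5.39-fold higher with the inhibitor (levels 4.87 and 7.30, difference 2.43, SD 1.09), in 16 of 16 probesets. Gfi1b was 2.95-fold higher (levels 8.41 and 9.93, difference 1.56, SD 0.40), in 7 of 7 probesets. The other members of the LSD1 complex and its partners did not pass the size rule: 2 of the 18 measured members were higher, namely Gfi1 and Gfi1b, and none was lower. Among the others, Rcor1, which encodes the scaffold CoREST, differed by -0.04 (0.07 as a mean over probesets), Hdac2 by 0.09, Rcor2 by 0.47 and Snai1, a repressor that also binds LSD1, by 0.93. Hdac1 differed by 0.07 and turned to -0.0049 when a level-dependent trend was removed. The median of the list was 0.11, at percentile 68.1 among 10000 random lists matched on level. Its mean, which includes the large differences of Gfi1 and Gfi1b in full, was 0.32 at percentile 99.1.

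**Figure D2:**
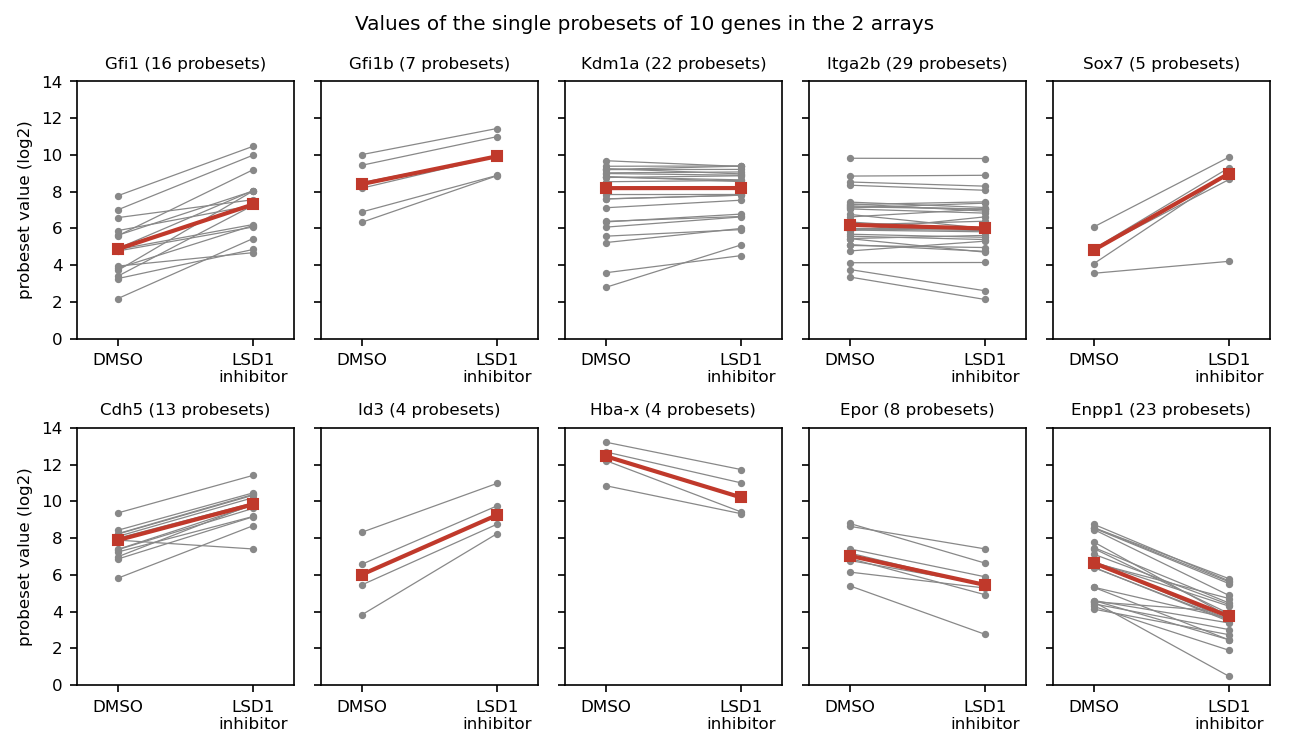
Values of single probesets (log2) of 10 genes in the DMSO array and the LSD1 inhibitor array, with grey lines joining the values of 1 probeset and red squares at the median in each array. All 16 probesets of Gfi1 and all 7 of Gfi1b are higher with the inhibitor, all 23 of Enpp1 and all 8 of Epor are lower, and the medians of Kdm1a and of Itga2b, the gene of the sort marker, lie near the same value in both arrays, while some of their single probesets differ more.

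Endothelial genes were higher in the inhibitor array as a group. Of 32 measured members of the endothelial list, 16 were higher past the size rule, 1 was lower and 15 were neither. The median difference was 1.06 (2.08-fold), and no random list of the same size and level reached it (percentile 100). Besides Sox7 and Ramp2, the higher members included Cdh5, which encodes VE-cadherin and differed by 2.11 (SD 0.82 over 13 probesets), She (2.18, SD 1.61 over 9 probesets, and between 1.19 and 3.16 over the alternatives), Adgrl4 (2.03), the junction protein gene Esam (1.97), Cd93 (1.81), Egfl7 (1.63), Plvap (1.61), Ecscr (1.49), Ets1 (1.47), Erg (1.26), Sox18 (1.25), Rasip1 (1.23), Flt1 (1.22) and Thsd1 (1.10). The lower member was Lyve1, a marker of lymphatic and some yolk sac endothelium. Cd34 (-0.53) and Robo4 (-0.10) were also below 0 without passing the rule. Kdr, which encodes FLK1, the marker used to isolate the mesoderm cells, differed by 0.79 with 29 of 30 probesets higher and did not pass the size rule. In the arterial and Notch list, 3 of 15 measured members were higher and none was lower: Hey2, a Notch target, by 2.32, the receptor gene Notch1 by 1.38 and the arterial ephrin gene Efnb2 by just over 1 (SD 0.47, 12 of 12 probesets). The list median was 0.24 at percentile 97.8, and it came back inside the central 95% of random lists in 6 of 18 alternatives. In 2 of the 6 the median was still 0.24, and the random lists alone moved the percentile, so the list lies at the limit.

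Erythroid genes were lower as a group. Of 23 measured members, 14 were lower past the size rule, none was higher, and all 23 had a difference below 0. The median was -1.18, below that of all 10000 random lists (percentile 0). The embryonic alpha-like globin gene Hba-x had levels of 12.46 and 10.22 and differed by -1.60. Another embryonic globin gene, Hbb-bh1, with levels of 11.19 and 10.49, differed by -0.29 and did not pass the rule, nor did Alas2, the erythroid enzyme of the first step of haem synthesis, at -0.07. The mitochondrial iron importer gene Slc25a37 differed by -1.55, and by -0.87 with even-ranked probesets alone. Car2 was at -0.55 with odd-ranked probesets alone. The other members past the rule were Hemgn (-1.45), the spectrin gene Sptb (-1.38), the carbonic anhydrase gene Car2 (-1.19), the transferrin receptor gene Tfrc (-1.19), Epb42 (-1.18), Kel (-1.17), the anion exchanger gene Slc4a1 (-1.15) and the erythroid transcription factor gene Klf1 (-1.12), with Trim10, Hbb-b1, Hbb-y and Epor as given above. The transcription factor gene Gata1, needed for red cells and megakaryocytes, differed by -0.73 in 9 of 9 probesets without passing the size rule. In the megakaryocyte and platelet list, 3 of 19 measured members were lower and none was higher, with a median of -0.29 at percentile 0. They were Pf4, P2rx1 and the thrombospondin gene Thbs1 (-1.28, SD 0.37 over 23 probesets). Itga2b itself, the gene of the sort marker, differed by -0.12 (SD 0.44 over 29 probesets).

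Transcription factors of blood went in different directions. Of 22 measured members, 4 were higher and 1 was lower. The higher ones were Gfi1, Gfi1b, Gata2, a factor of blood stem and progenitor cells that differed by 1.41 in 7 of 7 probesets, and Mecom (1.24), and the lower one was Klf1. Runx1, which is needed for hemogenic endothelium to form blood, differed by 0.11 (-0.07 as a mean over probesets), Spi1, which encodes PU.1, by 0.35, and Tal1 by -0.46. The list median of -0.05 was at percentile 0.49, whereas the mean of the same members was 0.14, of the opposite sign and at percentile 72.0. In the pan-haematopoietic list, 2 of 22 measured members were higher and none was lower, with a median of 0.15 at percentile 90.8. These were Cd53 (1.43) and the interleukin 10 receptor gene Il10ra (1.09), both below the table's median value in the control array. Lcp1 differed by 0.83, Laptm5 by 0.73, Kit, the stem cell factor receptor gene, by -0.66 and Ptprc, which encodes CD45, by -0.25 (0.13 with its brighter probesets alone).

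Markers of more mature white cells held few genes past the size rule. In the myeloid and macrophage list, 2 of 22 measured members were higher and none was lower, with a median of 0.13 at percentile 92.4: lysozyme gene Lyz2 by 1.77 (SD 0.15 over 5 probesets) and the mannose receptor gene Mrc1 by 1.49 in 26 of 26 probesets. Ctsg differed by 0.91 and Ncf4 by -0.90. None of the 8 measured lymphoid members passed the size rule. Their median was 0.33 at percentile 98.5, with Il7r at 0.74 and Dntt, dim in the control array, at 0.78. Dntt was at -0.06 when dim probesets were kept. The median was -0.06 when even-ranked probesets alone were used, which left 3 members. None of the 8 measured mast cell, basophil and eosinophil members passed it either, and their median was -0.20 at percentile 8.48, with Tpsb2 at -0.85 and Hdc at 0.76.

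Among the lists for other tissues the sorted cells could hold, the smooth muscle and mesenchyme list had 1 higher and 2 lower of 18 measured members and a median of -0.17 at percentile 0.050. With the brighter probesets of each gene alone that median was -0.0017 at percentile 25.6. Fbn1 was the higher member, and the matrix genes Dcn (-1.40, dim in the inhibitor array and at -0.65 with values below the table's median raised to it) and Postn (-1.32, 23 of 23 probesets) were the lower ones. In the mesoderm and cardiac list, 2 of 17 were higher, Hand2 (1.99) and Gata4 (1.06, and 0.58 with even-ranked probesets alone), and 1 was lower, Mef2c (-1.37, 29 of 29 probesets), with a median of 0.22 at percentile 97.1. None of 9 endoderm members passed the size rule (median 0.07, percentile 69.6). In the pluripotency list, 3 of 12 measured members were higher and none was lower, with a median of 0.46 at percentile 99.97. These were the transcription factor gene Klf2, which endothelium also expresses, at 1.17, the RNA-binding protein gene Lin28a at 1.12 and Dppa4 at 1.10. Pou5f1 (0.18), Nanog (0.05) and Esrrb (-0.12) did not pass the size rule. Of the 12 members, 10 were above 0 and 5 were brighter than the table's 75th percentile. With the brighter probesets of each gene alone, which left 6 members, the list median was 0.22 at percentile 91.6, Klf2 was at 0.72 and Dppa4 at 0.54.

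The extracellular matrix and TGF-beta list had 3 higher and no lower of 25 measured members, with a median of 0.30 at percentile 99.95. The 3 were Id3, Id2 (1.81) and Id1 (1.21), targets of BMP signalling. With the brighter probesets of each gene alone the median was 0.17 at percentile 94.7. Tgfbr2 differed by 0.99. Of 17 neuronal genes known as targets of the REST-CoREST repressor, to which LSD1 belongs, 2 were higher, Gap43 (1.80) and Nefl (1.54), and none was lower. Tubb3 differed by 0.95 and Gria2 by -0.91, and the list median of 0.07 at percentile 66.6 turned to -0.03 with the median gene set to 0.

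The remaining lists held few genes past the size rule. No member of the 34 measured cell cycle genes passed it, and the differences ran from -0.25 for Mki67 to 0.24 for Kif23. The median of that list was 0.01 at percentile 1.54, and it turned to -0.02 after quantile normalization. In the interferon list, Bst2 was higher (2.11) and Irf7 lower (-1.16, dim in the inhibitor array and at -0.43 with values below the table's median raised to it) of 14 measured members, with a median of -0.01 at percentile 45.8 that turned to 0.02 after quantile normalization. In the hypoxia and glycolysis list, the oxygen sensor gene Egln3 was the single member of 16 past the rule (1.06), Pgk1 differed by 0.78, and the median was 0.11 at percentile 68.8. None of 11 p53 targets passed the rule (median 0.06, percentile 43.8, turning to -0.01 with a level-dependent trend removed). None of 11 immediate early and dissociation stress genes did (median -0.03, percentile 6.84, turning to 0.0009 with each array centred), nor did any of 18 housekeeping genes (median 0.08, percentile 49.5). Of the 22 lists, 10 lay outside the central 95% of their random lists, 5 above and 5 below. Lists of randomly drawn genes would place 1.1 of 22 there. Genes of a preset list can vary together between any 2 samples, so this contrast does not exclude chance. The endothelial, erythroid and megakaryocyte lists stayed outside in all 18 alternatives, and the other 7 of the 10 came back inside or turned sign in at least 1. This percentile compares lists within these 2 arrays and not the conditions across replicates.

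**Figure D3:**
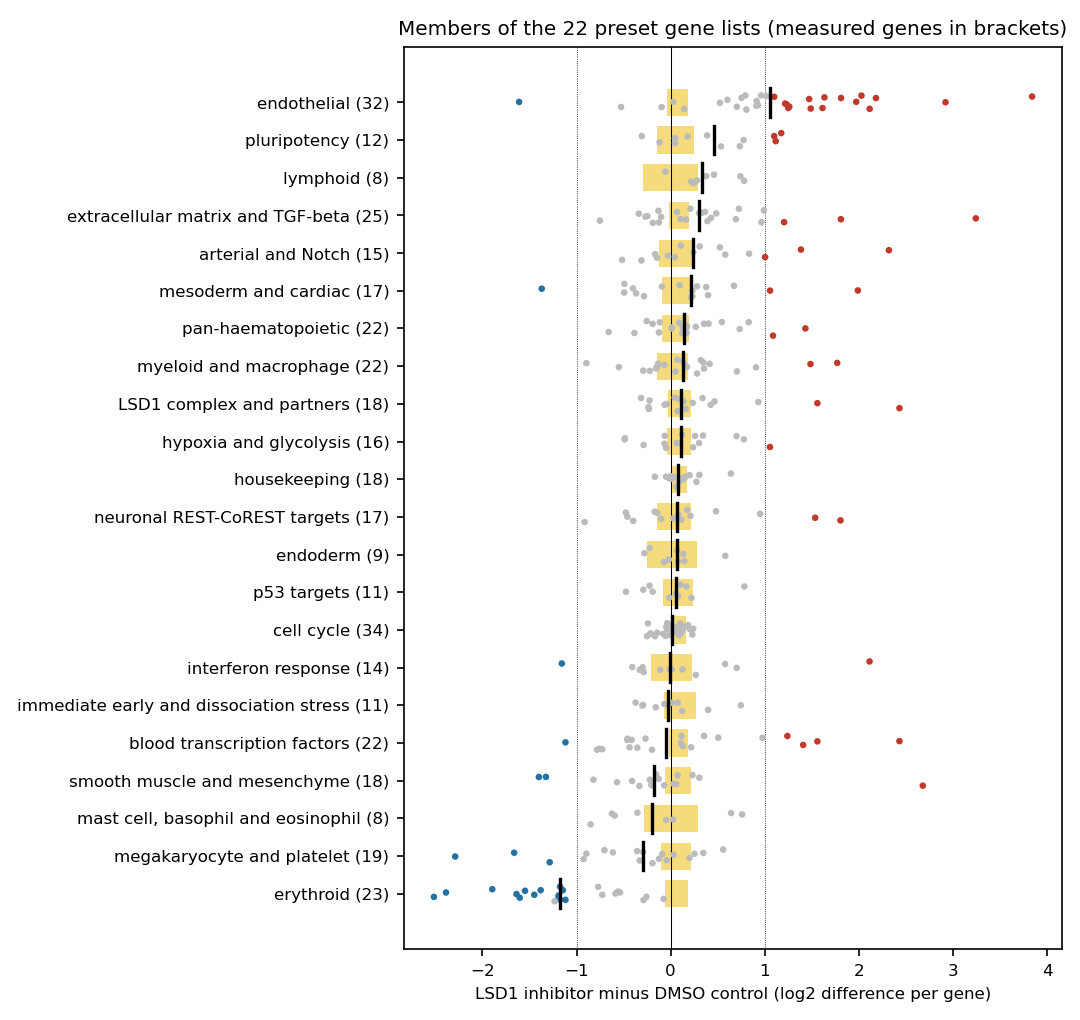
Log2 difference (LSD1 inhibitor minus DMSO control) of each measured member of the 22 gene lists, with a black bar at the list median, a yellow band over the central 95% of the medians of random lists matched on level, and dotted lines at 2-fold. Red and blue points are members past the size rule upward and downward. The endothelial median of 1.06 and the erythroid median of -1.18 lie furthest from their bands.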

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

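Large differences were also seen in probesets that have no gene name here and that the comparison of genes does not use. Of 383306 such probesets that were bright, 686 were at least 8-fold higher in the inhibitor array and 732 at least 8-fold lower. Per 10000 bright probesets these are 17.9 higher and 19.1 lower. Among bright probesets with 1 gene name the figures were 19.4 higher and 8.68 lower. A surplus of higher over lower values was seen in probesets with 1 gene name and not in those without. The sets are not matched on level. The median of all 1-gene probesets was 4.72 in the control array and 4.79 in the inhibitor array, against 3.18 and 3.16 for the whole table. A probeset can count as bright through 1 array, so a dim value in the other can give such a size. With no replicate, the share due to noise is not known. The 8-fold size was chosen after the data were seen, and no explanation was tested.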

How the results depend on the processing

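The 3 added alternatives (values below the table's median raised to it, the median gene difference set to 0, and lists without shared members) were chosen after the data were seen, and so was the rule by which a list's median is said here to depend on a setting. A first version of that rule asked whether a median moved by more than 1 SD of the medians of random lists. It would name 84 of the 393 list values, 10 of the 18 endothelial ones among them, and it was replaced after its result had been seen, partly because it named so many. The rule used asks whether the median stays on its side of the central 95% of random lists and keeps its sign. By it 353 values stayed, 25 came back inside, 7 went outside and 8 turned sign, and 65 of the 84 moved values are among those that stayed. Another 23 medians turned sign within the central 95%.

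Genes past the size rule numbered 259 higher and 85 lower. They numbered 169 and 51 with the brighter probesets of each gene alone, 641 and 439 with at least 1 bright probeset, 155 and 44 with at least 8, 882 and 402 at 1.5-fold, and 70 and 18 at 3-fold. With values below the table's median raised to it there were 51 lower genes and 193 higher. In the other alternatives the counts stayed within 1.5 times. Higher genes made up 75.3% of those past the rule, 69.5% with the trend removed, 67.8% with the median gene at 0 and 59.4% with at least 1 bright probeset.

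The endothelial median stayed between 0.84 and 1.24, the erythroid between -1.30 and -0.85 and the megakaryocyte between -0.44 and -0.18, outside the central 95% in all 18 alternatives (the endothelial list has no shared members to leave out). The arterial and Notch median came back inside with the trend removed (0.179), no filter (0.155), brighter probesets (0.198), probesets with several genes kept (0.241), the floor at the 20th percentile (0.241) and no shared members (0.175). The blood transcription factor median turned to 0.101 with the filter at the 75th percentile, 0.076 with odd-ranked probesets and 0.14 as a mean, and came back inside with brighter probesets (-0.018) and unmatched random lists (-0.045). The lymphoid median came back inside with the trend removed (0.216), no filter (0.0070), brighter probesets (0.171), at least 1 (0.263) or 8 bright probesets (0.218) and odd-ranked probesets (0.170), and turned to -0.056 with even-ranked ones. The pluripotency median came back inside with brighter probesets (0.219), at least 8 (0.046), odd-ranked (0.221) and even-ranked probesets (0.135). The cell cycle median turned to -0.021 with quantile normalization, -0.049 with the trend removed, -0.042 with brighter probesets and -0.046 with the median gene at 0. It came back inside with at least 8 bright probesets (0.0084), odd-ranked (0.027) and even-ranked ones (0.0077) and unmatched random lists (0.013). The extracellular matrix median came back inside with brighter (0.174) and even-ranked probesets (0.206), and the mesenchyme median with brighter probesets (-0.0017). Outside the central 95% went the myeloid median with no filter (0.144), the mean over probesets (0.227) and the mean over members (0.214), the mast cell median with unmatched lists (-0.20), the LSD1 complex as a mean (0.321), and the mesoderm median with quantile normalization (0.230) and without shared members (0.216). The mesoderm list has no shared members, and the arterial median of 0.241 is the main one, so in these 3 cases the random lists alone moved the percentile. The split and stricter settings leave fewer members. Other causes were not tested.

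Of 80 named genes past the size rule, 57 passed it in every alternative that measured them. Of 1865 values of named genes, 1856 moved by less than the SD over probesets, and 9 by more. In 10 named genes, 9 of them not past the rule, a value turned sign or reached 0. Aadacl2fm1, past it, turned to 0.033 with no filter, and the cause was not tested. Low signal limits the sizes of differences whose dimmer array lies below the table's median. A pseudocount of 16 in place of 1 was not run because the values are logarithms. No paired analysis was possible because each group has 1 array.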

Other observations

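All 7 lists in the next paragraph, with their versions that leave out members, the grouping of genes by symbol and all 7 tests in the later ones were chosen after the results were seen.

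Lower values were also seen in 2 lists of red cell genes that overlap the erythroid list in part, by 2 of 8 measured genes of haem biosynthesis and 7 of 13 of the membrane skeleton. Of the 8 genes of haem biosynthesis, 7 were below 0, with a median of -0.58 at percentile 0 among random lists, though none passed the size rule. Cpox differed by -0.90 and Uros by -0.86, while the enzymes of the first step were at -0.07 (Alas2, the erythroid form) and 0.49 (Alas1, the form of all tissues). Without the erythroid list's members, 6 genes of haem biosynthesis had a median of -0.60 at percentile 0. Of the 13 membrane skeleton genes, 5 were lower past the size rule and none was higher, with a median of -0.77 at percentile 0. These were Tmod1, Sptb, Epb42, Kel and Slc4a1, and 4 of them are also in the erythroid list. Without those of that list and Tmod1, named among the largest differences, 5 genes had a median of -0.25 at percentile 0.12, and none passed the rule. All 6 measured Gimap genes, GTPases best known from lymphocytes, were above 0 (median 0.55, percentile 99.8), and 2 were past the size rule, Gimap4 (3.22) and Gimap9 (2.30), both dim in the control array. Gimap4 led to the choice of this list, and the 5 others had a median of 0.53 at percentile 99.3. Of 11 genes that respond to BMP through SMAD1/5, 10 were above 0 and 3 were higher past the rule, with a median of 0.31 at percentile 98.9. The 3 were Id1, Id2 and Id3, the genes that led to the choice of the list. Without them the median of 8 genes was 0.19 at percentile 85.9, with Id4 at 0.22 and Smad6 at 0.69. Of 19 measured Hox genes, Hoxd9 alone passed the size rule (1.07), and the median was 0.11 at percentile 78.3. None of 15 histone lysine demethylase genes passed it (median -0.07, percentile 2.38), and none of 21 axon guidance genes did (median 0.01, percentile 27.3).

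Genes grouped by the letters of their symbols gave a negative result. Of 492 groups with at least 5 measured genes, none lay beyond all 2000 of its random lists on either side.

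The endothelial list was higher and the erythroid list lower in the inhibitor array. A lower share of erythroid cells as the only cause would raise all genes that erythroid cells lack by a like amount. Among members brighter than the table's 75th percentile, however, the endothelial median (1.25, 23 genes) exceeded the mesenchyme median (-0.10, 12 genes) by 1.35. The SD of such a gap between random lists was 0.096. The excess of 1.35 argues against that cause only if erythroid cells lack the mesenchyme genes, which these arrays do not show. A level-dependent trend between the arrays is argued against by the gap of 2.24 between the 2 list medians, which was still 2.22 after its removal; quantile normalization decides nothing, since the sorted values were nearly equal already. A larger share of endothelial cells in the CD41 sort and higher expression per cell cannot be told apart. Of the 23 brighter endothelial members, 22 were above 0, as either would give, and the sort gate can set such shares. The exception among these 23 was Cd34, at -0.53 with 10 of 12 probesets lower. Lyve1 (-1.61) and Robo4 (-0.10), also below 0, were too dim to be among them. Brightness was judged on the mean of the 2 arrays, and 18 members lay above that limit in the control array itself. Some of the 23 therefore entered through the inhibitor array, where they were higher. Whether the inhibitor is the cause was not tested.

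More genes were higher than lower with the inhibitor. The share of higher genes among those past the size rule was 75.3%. Scaling between the arrays as the whole cause is argued against by a share of 67.8% with the median gene difference set to 0, the lower of 2 corrections. Dim values are argued against by a share of 79.1% once all values below the table's median were raised to it. A difference in the mix of cells stays open, and there is no replicate to show how such a share varies between arrays of the same condition.

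Gfi1 and Gfi1b, the repressors named in the title of the series, were both higher with the inhibitor. The Gfi1 difference exceeded that of Gfi1b by 0.872, with an SE over probesets of 0.312 that treats probesets as independent. This does not decide whether Gfi1b RNA bound to Gfi1 probesets, because the 2 genes lie at different levels. The Gfi1b probeset dimmest in the control array went from 6.33 to 8.87, and the brightest from 10.02 to 11.44, so the difference varied with level. Of the 18 endothelial members above the table's 75th percentile of 4.84 in the control array, 4 differed by more than Gfi1b. That bears on a larger share of endothelial cells only if such cells express Gfi1b, which these arrays do not show. Such a share and higher expression per cell therefore cannot be told apart here. Whether the inhibitor is the cause was not tested.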
